A study of Mus musculus with 6 samples.

How the data were processed

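Poly(A)-selected RNA of mouse lung endothelial cells in primary culture was sequenced in 6 libraries, 2 labelled wild type and 4 labelled knockout for Zmpste24. Per the labels' protocols and the series design text, cells were isolated with magnetic beads against CD31 and ICAM2, grown to confluence without passage or treatment, and sequenced as single-end reads of 100 nt. Samples came from 2 cohorts of mice, per the labels, which assign no sample to a cohort. Nothing in the labels says that each library came from a separate animal, so p-values measure the spread between these libraries, which may be partly technical. Library names here are the genotype and the number in the title.

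The deposited table holds, for 53735 genes, a normalized count signal per library, which the authors obtained by dividing read counts by a size factor of each library. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.36, aligned with STAR 2.6.0c to GRCm38.p6 and counted with featureCounts of Subread 1.6.1. The series design text names other tools, Trimmomatic 0.32, STAR 2.4.2a and HTSeq with GENCODE release M17, followed by DESeq2 1.10.1 for normalization. Which of these made the table is not given in the sources used here. Whether counting used the strand is likewise not given, so reads of overlapping or antisense genes, and of near-identical copies, may be shared or lost.

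Each library's values were whole multiples of its smallest value above 0. Whole reads were recovered for 100% of values in every library, within a tolerance of 1e-06 of a read. The recovered reads gave 32699024 to 45613685 per library. At the lowest mean tested, 10 normalized counts, counting alone gives a coefficient of variation of about 31.6%. The median tested gene had a mean of 828 normalized counts. No pair of libraries within a genotype agreed within sampling noise, with a chi-square per gene of 28.4 to 438, so all 6 were kept as separate libraries.

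Because the deposited unit is normalized, the main test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean trend) on log2(normalized count + 1), with genotype as the sole term. The fold changes of low genes are understated on that scale. The 15229 genes with a mean of at least 10 normalized counts over the 6 libraries were tested, with Benjamini-Hochberg adjustment and a threshold of 0.05, the threshold of the series design text. Adjusted p-values of single genes are from limma unless another tool is named. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, two-sided, adjusted over the 29 lists with at least 5 tested members. Camera with an estimated correlation and fry were run beside it.

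Choices made before the data were examined were the groups, the tests, the gene lists and the rule for named genes. That rule took Zmpste24, the lamins and 14 endothelial and senescence genes whatever their result, of which 1 is not reported here. It also took up to 10 genes per direction with the largest change among called genes of mean at least 50 with separated groups, leaving out predicted genes and clone names. From each list it took the called or the most abundant members. These and the genes chosen later came to 129, which were narrowed by hand to the 79 reported here after their values had been seen, partly to limit the number of genes flagged for a library far from the others. Other settings tried were other pseudocounts, filters, scalings, array weights, no trend, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, the title number as a block, and each library left out in turn. With the title number as a block, knockout 3 and knockout 4 share their number with no wild type library. They then add nothing to the genotype difference, which rests on wild type 1 and 2 and knockout 1 and 2.

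After the values were seen, wild type 1 and knockout 1 were found to stand apart from the other 4 libraries. The 2 sets of libraries, both holding each genotype, were then entered as a term in limma, edgeR and DESeq2, and the 4 libraries of the second set were tested alone. Results named "with the library set as a term" come from these fits. Differences within a set are knockout 1 minus wild type 1, and knockout 2, 3 or 4 minus wild type 2. Genes that these fits called were named after their values were seen.

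The fits were tested on simulated data, 10 simulations of the 15229 genes with the real means of each library set, the real library sizes and 200 changed genes. The changed genes were drawn from those with a mean of at least 50 normalized counts. The spread was estimated with the library set as a term. The recovery rates therefore do not cover lower genes, and the simulated setting is that of the fits with this term. For knockout against wild type, limma with genotype alone recovered 3.1% of 2-fold and 50.3% of 4-fold changes. With the library set as a term it recovered 59.2% and 92.7%, with 6.92% of its calls false. DESeq2 with that term recovered 80.8% and 97.0%, with 29.0% of its calls false. Genomic positions are those of GENCODE release M21 on GRCm38, matched by symbol for 13346 genes (87.6% of those tested). Near-identical copies were searched with blastn among the transcripts of that release, at a minimum of 90% identity over 200 nt.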

Results

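Expression was measured in primary lung endothelial cells of mice with and without Zmpste24, the metalloprotease that completes the maturation of prelamin A to lamin A. Its loss in mice is a model of progeroid disease, and the series asks about endothelial dysfunction in Hutchinson-Gilford progeria. The 2 wild type libraries held 40582588 and 32699024 reads, and the 4 knockout-labelled libraries 40676474, 44273585, 45613685 and 36844042. Between 21074 and 22524 genes had at least 1 read. The fibronectin gene Fn1 was the most abundant gene in all 6 libraries, and the 10 most abundant genes took 5.90% to 6.97% of reads.

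Wild type 1 and knockout 1 stood apart from the other 4 libraries, among others in macrophage, contractile and endothelial genes. Lyz2, which encodes a macrophage lysozyme, stood at 856 and 718 normalized counts in these 2 libraries and at 18131 to 27455 in the other 4. Chil3, a gene of alveolar macrophages, had 33.5 and 28.8 counts against 2835 to 5020. The smooth muscle actin gene Acta2 had 136402 and 115895 counts against 27520 to 54028, and the endothelial cadherin gene Cdh5 62133 and 33414 against 13135 to 22282. The cell cycle inhibitor gene Cdkn2a had 4585 and 4385 counts against 327 to 717. Across genes, libraries of the same set correlated at r = 0.978 to 0.990 and libraries of different sets at 0.908 to 0.935, whatever their genotype; genes are not independent replicates. The first principal component held 77.3% of the variance and separated the sets, and the second held 9.58%.

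**Figure D1:**
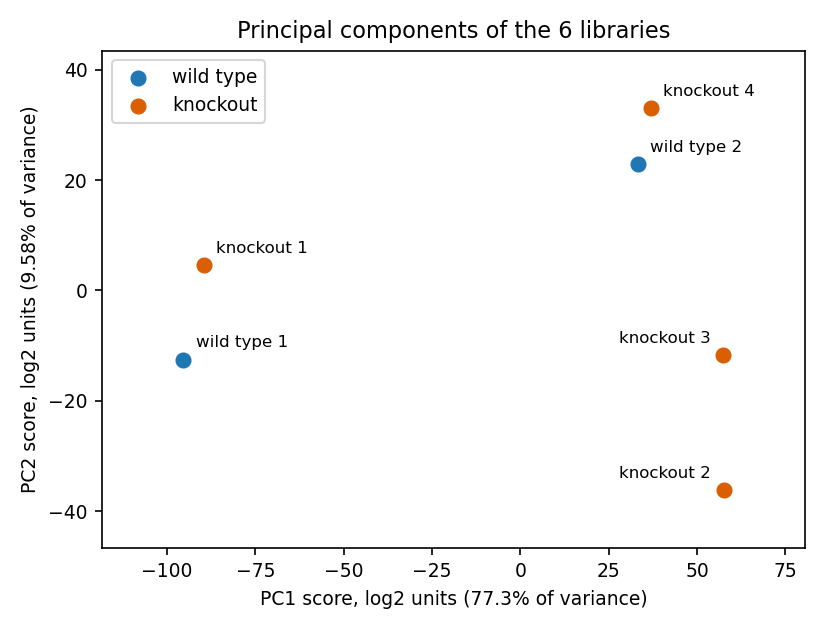
Scores of the 6 libraries on the first and second principal components of log2 normalized counts; each point is a library, coloured by genotype. Wild type 1 and knockout 1 lie apart from the other 4 libraries along the first component, which holds 77.3% of the variance.

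Genes of several other cell types were abundant in every library beside the endothelial genes. The collagen genes Col1a1 and Col1a2, typical of fibroblasts, reached 78891 to 173437 and 140619 to 184725 counts. Msln, the mesothelin gene of mesothelial cells, ranged from 4928 to 42001, and the endothelial gene Pecam1 from 7429 to 30000. Spp1, which encodes osteopontin, had 154368 to 248345 counts.

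**Figure D2:**
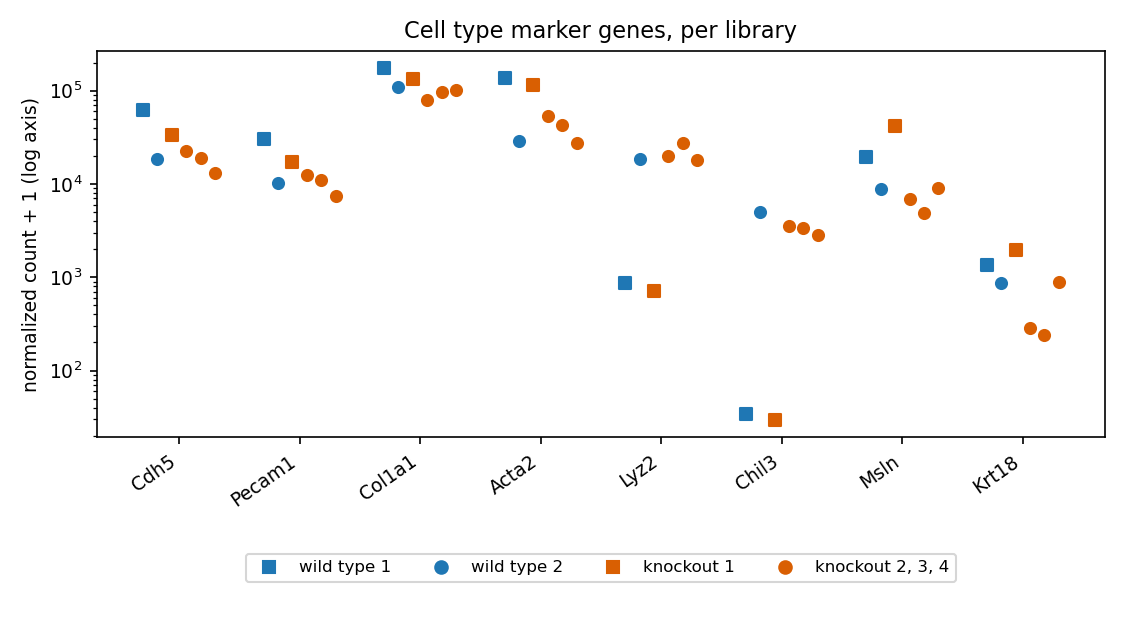
Normalized counts plus 1 (log axis) of marker genes of endothelial cells (Cdh5, Pecam1), fibroblasts (Col1a1), smooth muscle (Acta2), macrophages (Lyz2, Chil3), mesothelium (Msln) and epithelium (Krt18); each point is a library, squares for wild type 1 and knockout 1. Lyz2 is at 856 and 718 counts in these and at 18131 or more in the other 4.

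The first question was whether the targeted gene was lower in the knockout-labelled libraries. Zmpste24 (chromosome 4, positions 121059237 to 121098241, minus strand) had 5503 and 4148 normalized counts in wild type 1 and 2. It had 5079, 3764, 3599 and 3720 counts in knockout 1 to 4. The means were 4826 ± 959 (SD, n = 2) and 4041 ± 696 (SD, n = 4), a log2 difference of −0.26 ± 0.20 (SE; 95% interval −0.74 to 0.22; limma adjusted p = 1.00). Within the sets the differences were also small, with a log2 difference of −0.15 ± 0.06 (SE) with the library set as a term. The labels do not name the deleted part of the gene, so a count over the whole gene does not check the genotype labels, and directions below are those of the libraries labelled knockout.

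The genes of the nuclear lamina, whose precursor the Zmpste24 protease cuts, did not pass the test. Lmna, the gene of prelamin A, had 15925 ± 8652 (SD, n = 2) counts in wild type and 12691 ± 5030 (SD, n = 4) in knockout-labelled libraries, with a log2 difference of −0.02 ± 0.07 (SE) with the library set as a term. The B-type lamin genes Lmnb1 and Lmnb2 differed by −0.15 ± 0.33 and −0.06 ± 0.21, and with that term by −0.27 ± 0.28 and −0.13 ± 0.17 (log2, SE). Of the 32 tested genes of the nuclear lamina and prelamin A processing list, 0 were called, also adjusted over the list alone, and the list itself did not pass (median log2 −0.02, camera adjusted p = 0.494).

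The second question was which genes differed between genotypes. One transcript, RP23-357P12.1, had 15.7 and 11.5 counts in wild type and 668, 630, 622 and 744 in the knockout-labelled libraries. It was higher in 4 of 4, with a log2 difference of 5.52 ± 0.21 (SE, limma adjusted p = 0.00312). The sequence and function of this transcript were not analysed here. Its name is that of a genomic clone, which the rule for named genes leaves out, and it was named after its values were seen. Ndufs5, a subunit gene of respiratory complex I (chromosome 4, 123712710 to 123718202), had 507 and 484 counts in wild type and 1.03 to 5.47 in all 4 knockout-labelled libraries. It did not pass in the main test (log2 −6.78 ± 0.56, SE, limma adjusted p = 0.158). DESeq2 called Ndufs5 with genotype alone (adjusted p = 2.93e-45) and with the library set as a term (adjusted p = 2.32e-25), and edgeR only with that term (adjusted p = 0.0254). The sum of Ndufs5 and RP23-357P12.1 was 522 and 495 counts in wild type and 669, 635, 627 and 749 in knockout 1 to 4. The annotation holds a processed pseudogene, BC002163, that matches Ndufs5 at 99.4% over 319 nt and is not in the deposited table under that name. It may or may not be the locus of RP23-357P12.1, which was not tested. Whether reads moved between such entries cannot be told, so the 2 differences may not be separate changes. By limma, 1 gene of 15229 was called higher and 0 lower. An unadjusted p under 0.05 was reached by 143 genes, a share below 0.05, and with the library set as a term by 535. The fit with genotype alone leaves the difference between the library sets in the spread, which lowers this share. A low share here therefore does not tell whether genotype matters. EdgeR called 1 gene and DESeq2 7, of them 2 lower. The groups did not overlap in 713 genes (4.68%), against 13.3% if all libraries were exchangeable. Wild type 1 and 2 lie in different library sets, which makes such a gap rarer, so this share does not tell either. The call of RP23-357P12.1 was lost when knockout 2, 3 or 4 was left out, when limma called 0 genes (74, 52 and 126 at an unadjusted p under 0.05), though its log2 difference was then 5.55, 5.55 and 5.47 (adjusted p from 0.0672 to 0.0717); with the title number as a block it was 5.49 (0.483) and in the 4 libraries of the second set alone 5.73 (0.0997), also not called; without knockout 1 there were 2 calls, RP23-357P12.1 and Ndufs5.

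Other genes on chromosome 4 near Zmpste24 also separated the genotypes. Rhbdl2, which encodes a rhomboid protease (123787874 to 123829904), had 228 and 38.0 counts in wild type, 11.3 in knockout 1 and 0 in knockout 2, 3 and 4. Serinc2 (130253495 to 130279205) had 1326 and 478 counts in wild type and 231, 47.4, 15.4 and 45.4 in knockout 1 to 4. The histone deacetylase gene Hdac1 (129516104 to 129542713) had 2975 ± 246 (SD, n = 2) and 1993 ± 127 (SD, n = 4) counts. Gm10093, a processed pseudogene on chromosome 17 (78491582 to 78493025) that matches Hdac1 at 99.4% over 1444 nt, had 29.5 ± 4.21 (SD, n = 2) and 284 ± 93.5 (SD, n = 4). Reads of both may be shared, which makes these values uncertain; the annotation also holds a processed pseudogene that matches Rhbdl2 at 97.1% over 906 nt, so the same holds for Rhbdl2. Limma and edgeR called none of these 4 genes, with or without the library set as a term. DESeq2 with genotype alone called Gm10093 (adjusted p = 1.08e-08) and Hdac1 (adjusted p = 0.0279), but not Rhbdl2 or Serinc2. DESeq2 with the library set as a term called all 4, at adjusted p from 4.05e-12 for Gm10093 to 7.34e-05 for Rhbdl2.

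**Figure D3:**
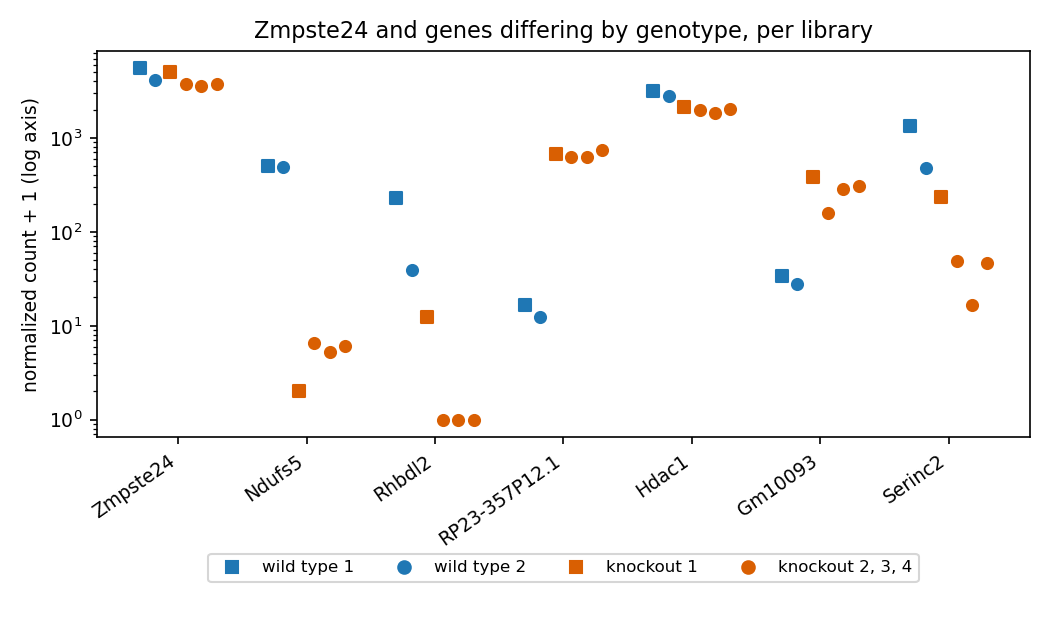
Normalized counts plus 1 (log axis) of Zmpste24 and of genes that separated the genotypes; each point is a library, coloured by genotype, squares for wild type 1 and knockout 1. Ndufs5 has 484 or more counts in both wild type libraries and at most 5.47 in the knockout-labelled ones, while Zmpste24 overlaps between genotypes.

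With the library set as a term, DESeq2 called 50 genes, 39 lower and 11 higher in knockout-labelled libraries, the lower ones including genes of endothelial cells. Flt1, which encodes a receptor of vascular endothelial growth factor, had 9339 and 4732 counts in wild type and 3854, 2724, 3136 and 2495 in knockout 1 to 4 (log2 −0.97 ± 0.15, SE, from limma with the same term). By the same measure Esm1, the gene of endocan, differed by −1.22 ± 0.20. The differences were −0.99 ± 0.20 for Angpt2, the angiopoietin-2 gene, and −0.82 ± 0.14 for Vwf, the von Willebrand factor gene. Plvap, the gene of the endothelial diaphragm protein, differed by −0.90 ± 0.18, the scavenger receptor gene Stab1 by −0.90 ± 0.18 and the growth factor gene Tgfb1 by −0.46 ± 0.09. Among genes with higher counts were Col8a1, a collagen gene of vessel walls (0.55 ± 0.09), Ctsc, the cathepsin C gene (0.49 ± 0.10), and Gucy1a3, a subunit gene of the nitric oxide receptor (1.19 ± 0.26). All 50 differed in the same direction in both sets, an agreement that choosing genes by a fit with this term favours; of all tested genes 49.9% shared their sign. Limma with the same term called 1 gene, with 535 at an unadjusted p under 0.05, and edgeR 2. In simulated data 29.0% of DESeq2's calls were false, a mean of 72.7 false calls per simulation beside 177.8 true ones. That share holds only for the number of genes changed in the simulation. The false calls alone outnumber the 50 calls made here, so how many of these 50 are false cannot be read from it.

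The third question was whether groups of genes moved together. Markers of lymphatic endothelium were lower in the knockout-labelled libraries, by a median log2 of −1.09 over 11 tested genes (camera adjusted p = 3.12e-07), and in each of the 4 libraries against the wild type of its set (−0.48, −0.72, −0.83 and −1.34), of which 3 share wild type 2. The adjusted p was 0.788 with an estimated correlation. With the library set as a term, 9 of the 11 genes were below 0 and 2 above. In both library sets alike, 7 were lower and 1 was higher. Prox1, the transcription factor gene of lymphatic identity, had 1792 and 1899 counts in wild type and 1703, 725, 636 and 657 in knockout 1 to 4, and so was lower by log2 −0.07 in the first set and −1.50 in the second; it passed neither over the list alone nor in DESeq2 with the library set as a term (adjusted p = 0.533). Reln, which encodes reelin, differed by log2 −1.33 ± 0.29, Mmrn1 by −1.10 ± 0.28, Flt4, the receptor gene of lymphatic growth factors, by −1.01 ± 0.20 and Lyve1, the hyaluronan receptor gene, by −0.86 ± 0.22 (SE, library set as a term). With that term these 4 genes passed in limma adjusted over the list alone and 0 over all genes, while DESeq2 called Reln and Flt4 over all genes; with genotype alone 0 passed either way.

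Venous genes and the wider endothelial identity list were lower as well. The venous list shares genes with the other lists, so these are not separate observations. Flt4 is also a lymphatic marker, and Vwf and Plvap are also endothelial identity genes. The 16 venous genes had a median log2 of −0.36 (camera adjusted p = 0.00744; adjusted p = 0.788 with an estimated correlation), and lay between −0.23 and −0.34 in each of the 4 knockout-labelled libraries against the wild type of its set. With the library set as a term the median was −0.18 and the list was called (adjusted p = 0.427 with an estimated correlation); Vwf, Plvap and Flt4 then passed in limma adjusted over the list alone and 0 over all genes, while DESeq2 called all 3 over all genes. The venous call was lost without wild type 1 (median −0.12, adjusted p = 0.234) and without knockout 4 (−0.33, 0.135). The 42 endothelial identity genes had a median of −0.58 (camera adjusted p = 1.01e-11; adjusted p = 0.788 with an estimated correlation). Their median was −0.61, 0.12, −0.11 and −0.52 in knockout 1 to 4 against the wild type of the set. Without wild type 1 it was 0.04 and the call was lost (adjusted p = 0.841); without wild type 2 it was −1.28. The list was called at −0.38 with the library set as a term (adjusted p = 0.794 with an estimated correlation) and at −0.18 in the 4 libraries of the second set alone. Of its members, Flt1 and Vwf passed in limma adjusted over the list alone with that term and 0 over all genes, and DESeq2 called Flt1, Vwf and Plvap over all genes, while the abundant Cdh5 and Emcn differed by −0.40 ± 0.28 and −0.51 ± 0.19 (log2, SE).

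Interferon-stimulated genes were higher as a group in the knockout-labelled libraries, though unevenly. Their median log2 was 0.35 over 49 tested genes (camera adjusted p = 3.12e-07; adjusted p = 0.788 with an estimated correlation), and 46 of the 49 were above 0 with the library set as a term. Against the wild type of the set, the median was 0.46 in knockout 1 and 0.80 in knockout 3, but −0.04 in knockout 2 and 0.06 in knockout 4. Leukocyte and macrophage markers, at −0.21, 0.27, 0.87 and −0.02 in knockout 1 to 4, were also highest in knockout 3 but below 0 in knockout 1. Whether the 2 lists are linked was not tested. The antiviral gene Ifit1 had 347 counts in both wild type libraries and 720, 231, 1298 and 456 in knockout 1 to 4, and Isg15, a ubiquitin-like modifier gene, 513 and 355 against 1131, 211, 866 and 328. The abundant Ifitm3 differed by 0.47 ± 0.34, Lgals3bp by 0.24 ± 0.36 and Bst2 by 0.18 ± 0.27 (log2, SE). None of the 49 passed, over all genes or adjusted over the list alone. Without knockout 3 the median was 0.18 and the list was still called (adjusted p = 0.00105).

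The 35 tested NF-kB target genes, an inflammatory group, were also higher, by a median of 0.24 (camera adjusted p = 0.0193; adjusted p = 0.788 with an estimated correlation). The complement gene C3 differed by 0.89 ± 0.82, Lcn2, the lipocalin-2 gene, by 1.35 ± 1.33 and the colony-stimulating factor gene Csf1 by −0.65 ± 0.75 (log2, SE). These were, with the library set as a term, 0.40 ± 0.28, 0.64 ± 0.76 and −0.21 ± 0.24, and the list median was 0.17. Of the members 0 passed, over all genes or adjusted over the list alone. The call was lost without wild type 1 (median 0.06, adjusted p = 0.299), wild type 2 (0.26, 0.0874), knockout 1 (0.23, 0.0551) or knockout 3 (0.14, 0.214), with no filter (0.24, 0.0595) and in the 4 libraries of the second set alone (0.19, 0.0564). With the title number as a block the median was 0.10 and the list was called. Against the wild type of the set, the NF-kB median was 0.15, 0.19, 0.33 and −0.07 in knockout 1 to 4. Leukocyte and macrophage markers were at −0.21, 0.27, 0.87 and −0.02, the same order in knockout 2, 3 and 4 but the opposite sign in knockout 1. Whether the 2 lists are linked was not tested.

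Cell cycle genes were lower as a group, with opposite directions among the libraries. The median of 61 tested genes was −0.23 (camera adjusted p = 6.06e-04; adjusted p = 0.788 with an estimated correlation). It was −0.47, −0.92 and −0.22 in knockout 1, 2 and 3 against the wild type of the set, and 0.53 in knockout 4. Mki67, a gene expressed in dividing cells, had 3510 and 3343 counts in wild type and 2083, 1917, 3332 and 5119 in knockout 1 to 4; Top2a, the topoisomerase gene of dividing cells, had 4224 and 5999 against 2654, 2873, 4878 and 8570. The abundant Anln differed by −0.29 ± 0.46 and Rrm1 by −0.10 ± 0.33, and with the library set as a term by −0.18 ± 0.46 and −0.03 ± 0.32 (log2, SE). The list median with that term was −0.30, with 61 of 61 members below 0. The list was then called (camera adjusted p = 1.22e-04), but not with an estimated correlation (camera adjusted p = 0.830). Of the members 0 passed, over all genes or adjusted over the list alone. The list was not called without wild type 2 (−0.13, adjusted p = 0.312), knockout 1 (−0.14, 0.307) or knockout 2 (−0.02, 0.861), and its median was −0.50 without knockout 4. It was not called with array weights (−0.12, 0.343), DESeq2 (−0.10, 0.0866) or in the 4 libraries of the second set alone (−0.20, 0.0564) either, and was called at −0.09 with edgeR and at −0.71 with the title number as a block.

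Lower medians were found in 4 more lists, each with an adjusted p = 0.788 with an estimated correlation and 0 members called by limma, over all genes or adjusted over the list alone; DESeq2 with the library set as a term called 1 member, Tgfb1 of the TGF-beta list. Genes of TGF-beta response and endothelial-to-mesenchymal transition had a median of −0.26 over 37 genes (camera adjusted p = 0.00152), vasoprotective and anticoagulant genes −0.20 over 29 (0.0109), cholesterol and isoprenoid synthesis genes −0.21 over 29 (6.06e-04) and oxidative phosphorylation genes −0.04 over 50 (0.0477). With the library set as a term these medians were −0.10, −0.10, −0.07 and 0.00 in limma; the last list was then not called in limma, edgeR or DESeq2, and the cholesterol list not in edgeR (−0.05, adjusted p = 0.0708). With that term and an estimated correlation the adjusted p were 0.427, 0.427, 0.794 and 0.993. Without wild type 1 the medians were 0.06, 0.03, 0.06 and 0.05, and none of these lists was called. The vasoprotective list was also lost without knockout 4 (−0.16, adjusted p = 0.116), with the title number as a block (−0.12, 0.105) and in the 4 libraries of the second set alone (−0.10, 0.0994), the cholesterol list with that block (−0.02, 0.473) and the TGF-beta list in the 4 libraries alone (−0.10, 0.0564). Oxidative phosphorylation was lost without knockout 2, 3 or 4 (adjusted p from 0.184 to 0.226), under the TMM, equal-total and quantile scalings, with no filter, no trend or edgeR (0.0653 to 0.120; medians −0.04 to −0.03), with the block (0.951) and in the 4 libraries alone (0.804). The heme oxygenase gene Hmox1 differed by −0.52 ± 0.39, Anxa2, the annexin A2 gene, by −0.52 ± 0.65, and the mesenchymal filament gene Vim by −0.42 ± 0.60; the lipid synthesis genes Fasn and Scd2 differed by −0.37 ± 0.41 and −0.13 ± 0.18 (log2, SE). The same 5 genes differed with the library set as a term by −0.29 ± 0.08, −0.12 ± 0.11, −0.06 ± 0.11, −0.12 ± 0.06 and −0.14 ± 0.17.

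**Figure D4:**
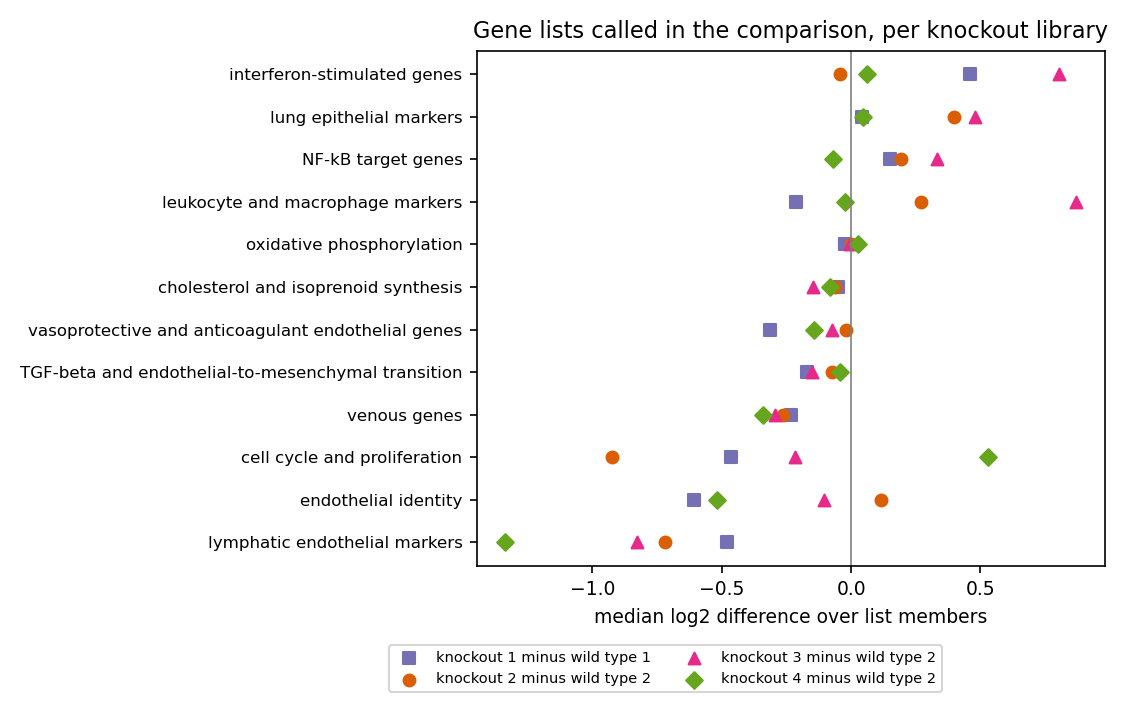
Median log2 difference over the tested members of each of the 12 called gene lists, for each knockout-labelled library minus the wild type library of its set; each point is 1 library. Lymphatic markers lie at −0.48 to −1.34 and venous genes at −0.23 to −0.34, whereas cell cycle genes lie at −0.92 in knockout 2 and 0.53 in knockout 4.

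Marker lists of 2 other cell types were higher with genotype alone. Leukocyte and macrophage markers had a median log2 of 1.12 over 23 genes (camera adjusted p = 0.0477) and lung epithelial markers 1.02 over 16 (0.0213), both with an adjusted p = 0.788 with an estimated correlation. The leukocyte median with the library set as a term was 0.12 in limma and the list was not called (adjusted p from 0.105 in DESeq2 to 0.151 in edgeR), while the epithelial list was called at a median of 0.23 (0.0498 in limma, 0.0326 in edgeR, 0.00879 in DESeq2; 0.794 in limma with an estimated correlation). In the 4 libraries of the second set alone the leukocyte list was called (0.35, 0.00951) and the epithelial list was not (0.17, 0.0560). Against the wild type of the set, leukocyte markers were at −0.21, 0.27, 0.87 and −0.02 in knockout 1 to 4, and epithelial markers at 0.04, 0.40, 0.48 and 0.04. The macrophage mannose receptor gene Mrc1 had 218 and 147 counts in wild type 1 and knockout 1 and 2188 to 4162 in the other 4 libraries, while the abundant epithelial keratin genes went against their list in knockout 2 and 3, with 320 and 266 counts of Krt8 against 906 in wild type 2, and 284 and 237 of Krt18 against 864. Without wild type 1 the medians were −0.64 and −0.06 and neither list was called. Leukocyte markers were also not called without knockout 2, 3 or 4 (medians 0.63 to 0.77, adjusted p from 0.163 to 0.356), nor epithelial markers without knockout 2 (0.65, 0.0545) or knockout 4 (0.87, 0.0833). Leukocyte markers were not called either with no filter, TMM or equal-total scaling, no trend or DESeq2, where the medians were 0.77 to 1.13 (adjusted p from 0.0505 to 0.0877), or the title number as a block (0.06, 0.254), nor epithelial markers with no filter (0.80, 0.0982), a filter at a mean of 50 (0.60, 0.216) or that block (0.36, 0.0569). Fibroblast markers (median 0.41), smooth muscle markers (−0.19) and mesothelial markers (−0.05) did not pass (camera adjusted p = 0.423, 0.430 and 0.602). Of 22 alternatives, they were called in 2, 3 and 3. The smooth muscle median was 0.31 without wild type 1 but −0.78 without wild type 2. The mesothelial median was 0.46 with the title number as a block but −0.41 in the 4 libraries of the second set alone.

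Of the 14 endothelial and senescence genes fixed in advance, 0 were called by limma, edgeR or DESeq2. The shear stress response genes Klf2 and Klf4 differed by −0.06 ± 0.24 and 0.16 ± 0.20, and the genes of nitric oxide synthase (Nos3), thrombomodulin (Thbd) and endothelin (Edn1) by −0.18 ± 0.49, −0.30 ± 0.71 and −0.52 ± 0.25. These 5 differed with the library set as a term by −0.12 ± 0.22, 0.07 ± 0.12, 0.07 ± 0.32, 0.06 ± 0.44 and −0.44 ± 0.22. The adhesion molecule genes Icam1, Vcam1 and Sele differed by −0.03 ± 0.12, −0.42 ± 0.59 and −0.68 ± 0.79, and with that term by 0.00 ± 0.09, −0.14 ± 0.41 and −0.20 ± 0.22. Cdkn1a, the gene of the cell cycle inhibitor p21, had 15910 ± 3559 (SD, n = 2) and 15849 ± 2355 (SD, n = 4) counts, a log2 difference of 0.00 with a 95% interval from −0.50 to 0.50, and of 0.09 ± 0.13 with that term. Cdkn2a differed by −1.17 ± 1.23 and by −0.42 ± 0.29 with the library set as a term. Trp53 differed by −0.09 ± 0.10, and the secreted factor genes Il6 and Ccl2 by 0.08 ± 1.04 and 0.12 ± 0.44; with that term the 3 values were −0.09 ± 0.08, 0.66 ± 0.50 and 0.37 ± 0.22 (all log2, SE).

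The remaining lists did not pass with genotype alone, and limma then called 0 of their members over all genes or adjusted over the list alone. With the library set as a term, limma called Vwf, Angpt2 and Ece1, the gene of an endothelin-converting enzyme (−0.41 ± 0.08), adjusted over the endothelial activation list alone, and Ank, a pyrophosphate transport gene (−0.64 ± 0.11), over the calcification list alone; Ece1 and Ank were named after their values were seen. DESeq2 with that term called these 4 over all genes, and also Tgfb1 of the secretory factors and Col8a1 of the extracellular matrix list. Targets of p53 had a median log2 of −0.09 (camera adjusted p = 0.176) and senescence-associated secretory factors one of 0.02 (0.708), with the abundant Igfbp3 at 0.32 ± 0.36, and at 0.17 ± 0.26 with the library set as a term. Endothelial activation genes had a median of −0.18 (0.0711), Notch and arterial genes −0.18 (0.0862), capillary genes 0.21 (0.132) and NRF2 antioxidant genes −0.09 (0.0563). Unfolded protein response genes had a median of 0.03 (0.890), and with the library set as a term −0.06 (0.0498 in limma and 0.0443 in DESeq2, but 0.0701 in edgeR and 0.427 in limma with an estimated correlation). Glycolysis and hypoxia genes (−0.09), extracellular matrix genes (−0.07), YAP targets (−0.01), MHC class II genes (0.04), BMP signalling genes (0.02) and calcification genes (0.05) had adjusted p from 0.129 to 0.890. The Notch list was called lower with edgeR (−0.26, 0.0432), DESeq2 (−0.28, 0.0413) and without wild type 2 (−0.55, 8.72e-04), knockout 2 (−0.28, 0.0415) or knockout 3 (−0.25, 0.0355), and higher without wild type 1 (0.14, 0.0129). Of 22 alternatives, endothelial activation genes were called in 5, NRF2 genes in 5, capillary genes in 4, p53 targets in 2 and extracellular matrix genes in 1. The mean and the median differed in sign for the BMP and calcification lists.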

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

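All tests of explanations in this part were chosen after the results were seen. Of 80 quantities compared among the 4 knockout-labelled libraries, 14 (17.5%) had 1 library far from the others, and in all 14 it was knockout 1. About 5% would be flagged by chance if these libraries were exchangeable. Knockout 1 is the only knockout-labelled library of the first set, so such flags may restate the split of the library sets. Wild type 1, of the same set, was not in this comparison. The genes compared are those the text names, a list narrowed after values were seen, partly to limit the number of flags, so these shares are not an unbiased count. Before that narrowing 18 of 129 genes (14.0%) were flagged, 16 of them with knockout 1 apart, and over all 15229 tested genes 1788 (11.7%), 1594 of them with knockout 1 apart. Knockout 1 was high, with the range of knockout 2 to 4 after each value, for Anxa2 (69687 against 21317 to 25543 normalized counts), Cpe (58700; 19392 to 23308), Ece1 (20267; 9089 to 10132), Fasn (13936; 6983 to 7343), Lmna (20235; 10157 to 10213), Prox1 (1703; 636 to 725), Prss23 (65869; 17898 to 20838), Vim (161808; 63227 to 65351), Vwf (2939; 819 to 971) and Zmpste24 (5079; 3599 to 3764). Knockout 1 also had 11.3 counts of Rhbdl2, where the other knockout-labelled libraries had 0. It was low for the macrophage genes Chil3 (28.8; 2835 to 3564), Lyz2 (718; 18131 to 27455) and Mrc1 (147; 2357 to 4162).

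The first pattern is that wild type 1 and knockout 1 stand together. Read depth is argued against, since the totals of both, 2 of 2, lie inside the range of the other 4 libraries. More leukocyte RNA in the other 4 libraries as the whole cause stays open. In both of these libraries 632 genes (4.15%) were at least 2-fold higher than in each of the other 4, against 765 lower. These counts do not decide it, because added leukocyte RNA would also lower the share of RNA from other cells. A candidate explanation is the 2 cohorts of mice that the labels mention, but no label assigns a cohort, so the component holding 77.3% of the variance cannot be told apart from other differences in culture or preparation. Genotype was not the shared factor, as each set holds both genotypes.

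The second pattern is that genes around Zmpste24 differ between the genotypes in both sets. Within 10 Mb of Zmpste24, 6 of 188 tested genes had a limma p under 0.01 with the library set as a term. Of 9594 windows of as many neighbouring genes, 0.97% held as many. That share is biased, since 4 of the 6 genes were seen before this window was tested. With the calls of DESeq2 left out of all windows, 2 were left there, and 14.1% of the windows held as many (median 1). That count leaves out the genes that raised the question, so it can miss a real excess. Strain sequence carried along with the targeted allele therefore stays a candidate explanation that these counts do not decide; a local effect of the allele itself was not tested, and the labels name no strain. Reads of Hdac1 counted at its near-identical copy Gm10093 are argued against as the whole cause of its lower count, since the sum of both was still lower (log2 −0.35 ± 0.06, SE); of 3 more copies in the annotation, 1 had 0 counts and 2 are not in the deposited table under their names, so reads counted there stay open. For Ndufs5 the sum with RP23-357P12.1 was 0.40 ± 0.11 higher in knockout-labelled libraries. Whether reads moved between them cannot be told, because the sequence of RP23-357P12.1 was not analysed here. The annotation used here holds a copy of Ndufs5, BC002163, 99.4% identical over 319 nt, which is not in the deposited table under its name. RP23-357P12.1 in turn was not matched by symbol in that annotation. Both names may stand for the same locus, which was not tested.

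The third pattern is the lower level of lymphatic endothelial markers. An unequal share of the library sets in the genotypes as the whole cause is argued against, since the median was −0.93 with the library set as a term, against −1.09 without it, and the list was called (camera adjusted p = 7.94e-06; 0.427 with an estimated correlation). A lower share of all endothelial cells stays open, since each comparison within a set rests on 1 wild type library. The lymphatic median minus that of the 42 other endothelial genes was −0.73 in knockout 2, 3 and 4 (two-sided permutation p = 0.00237 over genes, which are not independent), all against wild type 2, in which lymphatic RNA may have been high, and 0.13 in knockout 1 (p = 0.217). A genotype effect on lymphatic cells, or a different yield of them at isolation, may apply and was not tested.

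With 6 libraries there are 15 splits into 2 and 4, too few for a share under 5%. The genotype split called 1 gene, 3 splits including it called at least as many, and the highest other count was 7160, for wild type 1 and knockout 1 against the rest, which points to the structure of the libraries described above.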

How the results depend on the processing

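The fits with the library set as a term and the 4 libraries alone were chosen after seeing the data; all others were planned. Zmpste24 was lower and uncalled in every alternative, from −0.05 without wild type 1 to −0.46 without wild type 2. The count of 1 gene became 2, of which 1 lower, with a pseudocount of 5, quantile normalization, array weights or edgeR with the library set; 7 with DESeq2, 5 higher and 2 lower; 50 with DESeq2 and the library set, 11 higher and 39 lower; and 0, with 0 higher, in the 4 libraries alone (limma; 302 at an unadjusted p under 0.05). Leaving out each library gave 0 to 2 genes, 0 to 1 higher, 0 to 1 lower and 5 to 15 lists. Where 1 wild type library is left, it is assumed to vary like the other group. The title number as a replicate block gave 0 genes and 0 higher in limma. Its genotype difference rests on libraries 1 and 2 of each genotype, as knockout 3 and knockout 4 drop out of it. An unadjusted p under 0.05 was then reached by 781 of 15229 genes, near the share of 0.05 that chance gives. Deviations correlated at 0.84 for number 1 and 0.56 for number 2. Those of wild type 2 also correlated at 0.67 with knockout 3 and 0.53 with knockout 4. These values follow the library sets, and 2 shared numbers do not establish pairs. Of the 12 lists called, 0 were called with an estimated correlation and 0 with fry, while interferon-stimulated genes (0.18 to 0.86; adjusted p 1.49e-17 to 0.0097) and lymphatic markers (−1.27 to −0.73; 3.78e-11 to 0.00134) were called in all 22 other alternatives. Scaling moved the median of all genes by at most 0.02.

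With each library left out in turn, the list medians ranged over −1.28 to 0.0409 (endothelial identity), −0.829 to 0.0287 (vasoprotective), −0.681 to 0.0584 (TGF-beta), −0.552 to 0.142 (Notch), −0.459 to 0.0553 (cholesterol), −0.153 to 0.0540 (oxidative phosphorylation), −0.778 to 0.307 (smooth muscle), −0.638 to 3.23 (leukocyte) and −0.0635 to 2.50 (lung epithelial), and the direction of these 9, each called with or without wild type 1, turned without it. Among lists called in either of the 2 fits compared, the direction of the test turned with the library set as a term for the unfolded protein response (−0.0619 in limma and −0.0620 in DESeq2) and oxidative phosphorylation (−0.0012 in limma, 0.00615 in edgeR, −0.000326 in DESeq2). In the 4 libraries alone it turned, among such lists, for oxidative phosphorylation (0.00962), smooth muscle (0.294) and mesothelial markers (−0.414). Lists called in neither fit also turned and are not listed. Fewer libraries enter the last fits; the cause of the other changes was not tested. Of the gene lists' remaining values over all alternatives, 580 kept their side of the threshold, 72 lost a call and 27 gained one. The median tested gene had a mean of 828 counts. In simulated data with 2 wild type libraries, the changed genes had a mean of at least 50. Limma recovered 3.1% of their 2-fold changes with genotype alone and 59.2% with the library set as a term.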

Other observations

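Contractile and mesothelial genes differed among the knockout-labelled libraries in ways that genotype does not describe. Against the wild type of the set, smooth muscle and pericyte markers had a median log2 of −0.62, 0.65, 0.40 and −0.03 in knockout 1 to 4. Mesothelial markers were at 1.27, −0.25, −0.88 and −0.06; Msln had 42001 counts in knockout 1 against 19487 in wild type 1, and Lrrn4, another mesothelial gene, 10583 against 3478. In knockout 2 and 3 the contractile genes Acta2 (54028 and 42660 counts, 28540 in wild type 2) and Tagln (35817 and 25189, 22433 in wild type 2) lay above the wild type of the set. Knockout 4 lay closest to wild type 2, with r = 0.990 across genes.

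Near Zmpste24, the blood transcription factor gene Tal1 was lower (log2 −0.67 ± 0.16, SE) and the collagen gene Col16a1 higher (0.66 ± 0.16) with the library set as a term. Their unadjusted p were 0.00674 and 0.00853 in limma, and both were named after their values were seen. Tal1 is also a member of the endothelial identity list, which was lower as a group (median −0.38 with that term). Whether Tal1 follows its position or that list was not tested. Across genes, the genotype differences of the first and the second set correlated at r = 0.06 and shared their sign in 49.9% of genes, and genes are not independent replicates. The venous genes Cpe and Prss23, the most abundant of their list, differed by −0.22 ± 0.11 and −0.13 ± 0.15 (log2, SE, library set as a term).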
